A study of Arabidopsis thaliana with 12 samples.

How the data were processed

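Total RNA of rosette leaves from wild type (Col-0) and from green, green-white and white leaves of melinoe, an ethyl methanesulfonate mutant of AtFMN/FHY, was sequenced on a DNBSEQ platform from strand-specific libraries of polyadenylated RNA, per the labels' protocols. Plants were stratified for 48 h, kept for 2 weeks on medium with 1% sucrose before transfer to soil, and grown at 22 °C under 16 h light of 75 µmol m−2 s−1 and 8 h dark, per the labels' protocols. Reads were filtered with SOAPnuke 1.5.2 (options l 15, q 0.2 and n 0.05) and aligned to TAIR10 with HISAT2 2.0.4, per the labels' design text. The submitters' processing notes also name Bowtie2, RSEM and DESeq2 without versions or roles, and the annotation and the strand setting of the counting are not given in the sources used here.

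The authors deposited 3 tables, each comparing a melinoe leaf class with wild type. Per the file headers they hold read counts per gene and library, a log2 fold change by the authors, and the authors' p-value and q-value. The deposited counts are expected counts: about 92.5% of the values are whole numbers, and genes with near-identical copies carry fractions, so such genes are named as uncertain. The wild-type counts are the same in all tables. Each deposited table lists genes with at least 1 count in one of its 6 libraries. The union held 25169 genes, 23214 of them in all 3 tables, and the 9750 missing values were set to 0; the highest wild-type count of an unlisted gene was 0.9. All 25169 gene identifiers matched the TAIR10.1 reference, from which locus codes, coordinates and overlapping genes were taken. No plastid- or mitochondrion-encoded gene was present, and 1142 genes are annotated as pseudogenes. The 18 columns of TPM values per sample were not used. Columns were matched to groups through their names; they carry the letters A, B and C and the labels the numbers 1 to 3, with nothing to tie them, so no pairing was used.

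Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16, using TMM factors (0.903 to 1.12) and the quasi-likelihood test on all 12 libraries, with group means and 8 residual degrees of freedom. The low-count filter of edgeR left 19424 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and all 6 pairs of groups were compared. Levels are CPM values scaled by the TMM factors. These factors followed the groups, at 0.903 to 0.929 in wild-type and green libraries and 1.08 to 1.12 in green-white and white libraries. Small differences across this divide can therefore depend on the scaling. Pairs of libraries within a group differed by 1.57 to 3.86 chi-square units per gene, above sampling noise in each pair. Such an excess can also arise in library preparation, so it does not show that the libraries came from separate plants. Each library counted once. The common biological coefficient of variation was 0.0272, which is low for separate plants. So small a spread makes small differences pass the test, so sizes are given beside calls. Folds from groups with no counts use a floor of 3 counts per library, those with 1 to 3 counts a 95% counting interval; intervals and floors cover counting error only.

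Before the data were examined, 30 gene lists, the groups, the test, the alternatives and the rule for named genes were fixed. Lists with at least 2 tested genes (28 of 30) were tested against all other genes with camera in limma 3.58.1 at a preset correlation of 0.01, p adjusted over the 28 lists of a comparison. Each call was repeated with an estimated correlation, and where that ended the call its adjusted p is printed. The root list had no tested gene and the meristem list 1, KNAT1. KNAT1 gave −0.85 ± 0.70 in green (adjusted p = 0.31), 1.19 ± 0.49 in green-white (adjusted p = 0.027) and 1.94 ± 0.43 in white leaves (adjusted p = 8.0e-05) over wild type. Its mean level was low, 0.15 CPM in wild type and 0.08, 0.35 and 0.59 CPM in these leaf classes. The green-white call ended with DESeq2 (adjusted p = 0.098) and without wild type B (0.073), green-white A (0.067) or green-white B (0.096). Named genes are the flavin metabolism list; the 5 highest and 5 lowest log2 fold changes among called genes with a symbol, a mean of at least 5 CPM in the higher group and no overlap between groups; and, for each called list, up to 3 called members of largest change with the 1 of smallest adjusted p in the other direction. The values of a named gene may be given in other comparisons, and up to 4 members of smallest adjusted p may be named from an uncalled list. Members named from lists had no minimum level, so some of their folds start near 0 CPM.

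The workflow was tested on simulated data drawn from the wild-type means and the library sizes of these samples, with 200 genes changed in 1 group. For the comparisons of green, green-white and white leaves with wild type (18717, 18717 and 18715 genes), it recovered 74, 76 and 72% of changes of 1.25-fold, 94, 88 and 88% of 1.5-fold, 96, 96 and 98% of 2-fold and 100% of 4-fold, with 12, 7 and 13 false calls. Far fewer genes changed in the simulation than were called against wild type in the data (11363 to 15514), and their directions were balanced. The rates therefore do not cover scaling or false calls when most genes change. The alternatives for genes were DESeq2 1.42.0, RLE and upper-quartile factors, other low-count filters, fits of the 6 libraries compared, a 2-fold minimum and the removal of each library. Of these, list tests were repeated only with RLE factors and the removal of each library, and besides with an estimated correlation. Set tests of annotation terms, sums of seed storage genes and a replicate block by column letter were added after the data were seen.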

Results

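Rosette leaves of wild-type Arabidopsis thaliana (Col-0) and of melinoe, an ethyl methanesulfonate mutant of AtFMN/FHY, were profiled by RNA sequencing of polyadenylated RNA. AtFMN/FHY is the bifunctional riboflavin kinase and FMN hydrolase that makes the flavin cofactor FMN from riboflavin. The mutant was sampled as 3 leaf classes, labelled green, green-white and white, and each of the 4 groups held 3 libraries. The labels call these biological replicates and do not say whether a library came from 1 plant or from a pool, so p-values measure the spread between these libraries. Library totals lay between 25795702 and 26760055 estimated counts. A mean of 21551 genes had at least 1 count in wild type, 21698 in green, 22176 in green-white and 22398 in white leaves. The 100 most abundant genes took 31.8 ± 0.22% of the counts in wild type, 29.6 ± 0.57% in green, 20.6 ± 0.12% in green-white and 17.7 ± 0.085% in white leaves (SD, n = 3). The antenna gene LHCB1.3 was the most abundant gene in all 12 libraries, with a mean of 2.58, 2.95, 1.51 and 1.07% of the counts in the same order. It shares reads with near-identical copies, so its rank and share are uncertain.

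The mutated gene itself was not called in any comparison with wild type. FMN/FHY (AT4G21470) lies on the plus strand of chromosome 4, from 11431104 to 11433322 in TAIR10.1, and its 10 exons hold a coding region from 11431284 to 11433197. The annotated gene AT4G21480 overlaps it, and reads from the overlap could have been assigned to either gene. Its level was 23.3 ± 1.23 CPM in wild type, 22.1 ± 0.64 in green, 23.6 ± 0.12 in green-white and 24.4 ± 0.67 in white leaves (SD, n = 3). The log2 fold change over wild type was −0.07 ± 0.05 in green (adjusted p = 0.25), 0.02 ± 0.05 in green-white (adjusted p = 0.74) and 0.07 ± 0.05 in white leaves (adjusted p = 0.20). Here and below, CPM are counts scaled to library size. The value after ± beside a log2 fold change is its standard error from the model of all 12 libraries, with 3 libraries per group, and each gene said to rise or fall has its adjusted p under 0.05. A point mutation need not change the transcript level, so these values do not check the genotype labels.

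The other genes of flavin metabolism moved in both directions, and the list as a whole was not called against wild type. RIBA1 (AT5G64300), which carries out the first step of riboflavin synthesis, rose in all 3 leaf classes, by 0.57 ± 0.04 in green, 0.61 ± 0.03 in green-white and 0.63 ± 0.03 in white leaves. RIBF1 (AT5G23330), a plastid FAD synthetase, rose by 0.65 ± 0.07, 0.86 ± 0.07 and 1.70 ± 0.06 in the same order. FHY1 (AT1G79790), a plastid FMN hydrolase, rose by 0.20 ± 0.04 in green leaves and was lower in green-white (−0.62 ± 0.04) and white leaves (−1.21 ± 0.05). COS1, the lumazine synthase, fell in green (−0.20 ± 0.05) and green-white leaves (−0.20 ± 0.05). RIBA3 had 0.25 ± 0.04, −0.27 ± 0.04 and 0.06 ± 0.04, and PYRP2 had 0.20 ± 0.03, −0.11 ± 0.03 and −0.35 ± 0.03, the white value of RIBA3 being the one not called (adjusted p = 0.21). Of the 13 members, 6 were higher and 3 lower in green leaves (median 0.07, adjusted p = 0.35). The same counts were 3 and 7 in green-white leaves (median −0.11, adjusted p = 0.95). In white leaves they were 5 and 2 (median 0.07, and −0.01 under upper-quartile scaling, adjusted p = 0.57). NUDX23 fell by 0.21 in green and by 0.23 in green-white leaves, and RIBA2 (0.43 ± 0.05) and PYRR (0.36 ± 0.06) rose in white leaves.

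Green melinoe leaves, compared with wild type, gave the difference in the mutant leaf class labelled green. GSTU25 (AT1G17180), a glutathione transferase, rose from 0.124 ± 0.041 to 7.11 ± 0.21 CPM (SD, n = 3), a log2 fold change of 5.79 ± 0.24, and the dark-inducible dioxygenase DIN11 (AT3G49620) rose by 5.50 ± 0.07. The plant defensins PDF1.3 (AT2G26010, 5.17 ± 0.05), PDF1.2c (AT5G44430, 4.71 ± 0.05) and PDF1.2b (AT2G26020, 4.65 ± 0.08) followed, though these near-identical copies share reads and their separate values are uncertain. PYK10 (AT3G09260), the beta-glucosidase of endoplasmic reticulum bodies, was lowest at −4.79 ± 0.08, followed by the floral MADS-box factor SEP3 (AT1G24260, −4.04 ± 0.15) and the vegetative storage protein VSP1 (AT5G24780, −3.38 ± 0.05). The fatty acid desaturase ADS1 (−2.98 ± 0.18) and the reductase BEN1 (−2.96 ± 0.19) completed the 5 lowest.

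Several lists of the photosynthetic apparatus were lower in green leaves. Of the nuclear photosystem and electron transport genes, 26 of 34 tested members fell and 4 rose (median −0.21, adjusted p = 1.6e-05, and adjusted p = 0.24 with an estimated correlation). PSAN fell by 1.00, ferredoxin FD2 by 0.72 and PSAD2 by 0.64, while PSBS (0.12 ± 0.03) rose. Among the light-harvesting antenna proteins, 14 of 21 tested members fell and 5 rose (median −0.20, adjusted p = 0.00064, and adjusted p = 0.40 with an estimated correlation). LHCB4.3 (−0.79 ± 0.05) fell and LHCA5 (0.20 ± 0.03) rose. LHCB2.3 (−1.13 ± 0.03) was lower and shares reads with its copies. In chlorophyll biosynthesis, 18 of 26 tested members fell and 5 rose (median −0.13, adjusted p = 0.0499, and adjusted p = 0.15 with an estimated correlation). Glutamyl-tRNA reductase genes moved apart, HEMA1 (−1.02 ± 0.03) falling and HEMA2 (1.00 ± 0.04) rising, and protochlorophyllide reductase PORA (−0.99 ± 0.12) fell. The chlorophyll biosynthesis call ended under RLE scaling (adjusted p = 0.057) and without any single library except green-white C (adjusted p from 0.052 to 0.12). The regulators of photosynthetic genes GLK1 (−1.08 ± 0.03), GLK2 (−0.52 ± 0.03) and GNC (−0.75 ± 0.06) fell and GUN1 (0.38 ± 0.03) rose. Their list of plastid transcription and chloroplast regulators, with 11 of 19 members higher and 4 lower, was not called (adjusted p = 0.95). Also uncalled were the Calvin cycle (11 of 21 lower and 5 higher, median −0.08, adjusted p = 0.059) and photorespiration (5 of 17 lower and 7 higher, median 0.04, adjusted p = 0.83, median 0.00 under upper-quartile scaling). The same held for plastid ribosomal proteins (9 of 28 lower and 3 higher, median −0.02, adjusted p = 0.75) and chlorophyll breakdown (6 of 9 higher and 2 lower, median 0.13, adjusted p = 0.63). Carotenoid metabolism was not called either (8 of 15 higher and 5 lower, median 0.09, adjusted p = 0.51). From these lists, GS2 (−0.24 ± 0.03) and NYC1 (−0.68 ± 0.03) fell and SGR1 (0.41 ± 0.05) and ZEP (0.39 ± 0.03) rose.

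Hormone and stress lists rose in green leaves. In the oxidative stress and mitochondrial dysfunction list, 14 of 16 tested members rose and 1 fell (median 0.93, adjusted p = 3.5e-14). The list was led after GSTU25 by GSTU24 (3.21 ± 0.11) and the alternative oxidase AOX1D (2.57 ± 0.08). Of the abscisic acid, cold and drought genes, 15 of 17 tested members rose and 1 fell (median 0.67, adjusted p = 5.8e-17), among them LTI30 (2.59 ± 0.08), RD29A (1.74 ± 0.03) and COR15A (1.58 ± 0.05), with RD22 (−0.25 ± 0.03) falling. In the jasmonate list, 19 of 24 tested members rose and 5 fell (median 0.91, adjusted p = 1.1e-15). The jasmonate hydroxylase CYP94B3 (2.29 ± 0.05) rose, whereas the storage proteins VSP1 and VSP2 (−2.50 ± 0.03) fell. For ethylene and defensins, 9 of 14 tested members rose and 5 fell (median 0.88, adjusted p = 1.1e-12). ACS2 (2.78 ± 0.19), an enzyme of ethylene synthesis, and PR4 (2.08 ± 0.03) rose and ERF5 (−0.59 ± 0.04) fell. Of the salicylic acid genes, 14 of 24 tested members rose and 7 fell (median 0.27, adjusted p = 0.0022). FMO1 (2.12 ± 0.19) and PR5 (1.06 ± 0.04) rose, while WRKY62 (−1.44 ± 0.23) fell. In the senescence list, 10 of 17 tested members rose and 6 fell (median 0.43, adjusted p = 0.0499, and adjusted p = 0.11 with an estimated correlation). DIN2 (3.77 ± 0.13), a dark-inducible beta-glucosidase, NAC019 (2.34 ± 0.04) and WRKY75 (2.24 ± 0.10) rose and ASN1 (−1.85 ± 0.03) fell. The senescence call ended under RLE scaling (adjusted p = 0.052) and without wild type A, wild type B, wild type C, green-white B, white A and white B taken singly (adjusted p from 0.053 to 0.086).

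The iron homeostasis list rose in green leaves, 13 of 17 tested members being higher and 1 lower (median 0.94, adjusted p = 5.4e-11). IMA1 (AT1G47400, 1.50 ± 0.06) and BHLH39 (AT3G56980, 1.44 ± 0.08) rose together with BHLH38, whose counts were not whole. The regulator FIT (−1.05 ± 0.26) fell from 1.36 to 0.66 CPM. Of the antioxidant enzymes and ferritins, 10 of 19 tested members fell and 6 rose (median −0.09, adjusted p = 0.0034, and adjusted p = 0.11 with an estimated correlation). The iron superoxide dismutase FSD1 (−2.43 ± 0.03), the ferritin FER4 (−1.29 ± 0.10) and the catalase CAT3 (−1.19 ± 0.03) fell, and the chloroplast copper/zinc enzyme CSD2 (1.09 ± 0.03) rose. Among heat-shock proteins, 9 of 14 tested members rose and 1 fell (median 0.56, adjusted p = 0.0018, and adjusted p = 0.070 with an estimated correlation). HSP17.6C (3.60 ± 0.28) and HSP17.4 (2.93 ± 0.18) rose and HSP18.2 (−1.42 ± 0.33) fell. For anthocyanin and flavonoid genes, 14 of 19 tested members rose and 1 fell (median 0.52, adjusted p = 0.0034, and adjusted p = 0.11 with an estimated correlation). DFR (1.88 ± 0.08) and GSTF12 (1.82 ± 0.13) rose. In glucosinolate biosynthesis, 19 of 25 tested members fell and 5 rose (median −0.51, adjusted p = 1.5e-07). FMOGS-OX3 (−1.08 ± 0.05) and MYB29 (−1.03 ± 0.07) fell and MYB122 (2.80 ± 0.63) and CYP79B2 (0.72 ± 0.04) rose. MYB122 was low, with 0.055 CPM in wild type and 0.41 CPM in green leaves. Of the cell cycle genes, 17 of 19 tested members fell and 1 rose (median −1.03, adjusted p = 0.0091, and adjusted p = 0.10 with an estimated correlation). CYCB1;3 (−2.74 ± 0.49) fell from 0.76 to 0.11 CPM and CDKB2;1 (−1.71 ± 0.18) from 3.32 to 1.01 CPM. In the clock list, 9 of 12 tested members rose and 1 fell (median 0.29, adjusted p = 0.0051, and adjusted p = 0.080 with an estimated correlation), with PRR5 (0.89 ± 0.04) and TOC1 (0.71 ± 0.04) higher and LHY (−0.40 ± 0.05) lower.

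Markers of leaf cell types moved in the same comparison. Of the vascular markers, 9 of 13 tested members fell and 0 rose (median −0.61, adjusted p = 0.0010). The xylem genes XCP2 (−2.32 ± 0.11), CESA7 (−2.22 ± 0.23) and CESA8 (−2.18 ± 0.22) fell. Epidermis and trichome markers were lower too. There, 6 of 8 tested members fell and 1 rose (median −0.56, adjusted p = 7.3e-06), with CER1 (−1.35 ± 0.03), LTP1 (−0.89 ± 0.03) and TRY (−1.46 ± 0.19) falling and PROTODERMAL FACTOR 1, the gene PDF1, rising (0.88 ± 0.18). Guard cell (3 of 7 higher and 2 lower, median 0.11, adjusted p = 0.83) and floral lists (2 of 7 lower and 1 higher, median −0.01, adjusted p = 0.17) were not called. The list of flavin-dependent enzymes and photoreceptors was not called either (23 of 54 higher and 17 lower, median 0.07, adjusted p = 0.14, called at adjusted p = 0.045 without green A). Over all genes, 11363 of 19424 changed at an adjusted p under 0.05, 5592 higher and 5771 lower, and 2129 of them also differed at least 2-fold (980 higher, 1149 lower). The balance of directions depended on the fit, as 49.2% of the changed genes were higher as reported, 41.6% under upper-quartile factors, and 54.3 to 55.3% without any 1 of the wild-type or green libraries. The 3 libraries of one group all lay above those of the other for 11960 genes, 61.6% against the 10% given by chance. When adjusted over the list alone, the counts of members differed from those over all genes tested for the Calvin cycle list (5 higher and 13 lower), the plastid ribosomal protein list (3 higher and 6 lower), the anthocyanin list (14 higher and 2 lower) and the floral organ list (0 higher and 2 lower) and were equal for the other lists. The median, the mean and the test differed in sign for the plastid transcription and regulator list (median 0.14, mean 0.04, test direction down), which was not called.

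Green-white leaves, compared with wild type, had lower photosynthetic lists and higher stress and hormone lists. DIN2 (AT3G60140) rose from 0.826 ± 0.25 to 54.1 ± 1.76 CPM (SD, n = 3), a log2 fold change of 6.03 ± 0.09, and DIN11 rose by 6.38 ± 0.07. The glutathione transferase GSTU3 (AT2G29470, 6.31 ± 0.18) and the myo-inositol oxygenase MIOX4 (AT4G26260, 5.73 ± 0.20) were also among the 5 highest. SUC7 (AT1G66570), of the sucrose transporter family, had 1 count over the wild-type libraries against 1374 in green-white, a ratio of 1166 with a 95% counting interval from 209 to 46085. PYK10 was again lowest (−4.75 ± 0.08), followed by HFR1 (AT1G02340, −3.26 ± 0.12), a bHLH factor of far-red light signalling, DR4 (AT1G73330, −3.15 ± 0.08) and the cytochrome P450 gene CYP78A8 (AT1G01190, −3.15 ± 0.15). CIB1, a cryptochrome-interacting bHLH factor, went from 8.19 ± 0.42 to 0.961 ± 0.85 CPM, with 0 to 1.63 CPM in single green-white libraries, and it overlaps AT4G34540.

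Photosynthetic lists fell in green-white leaves. Of the antenna genes, 21 of 21 tested members fell and 0 rose (median −1.27, adjusted p = 7.5e-49), with LHCB4.3 (−1.52 ± 0.05) among members of whole counts and LHCB2.3 (−2.49 ± 0.03) and LHCB1.4 (−2.22 ± 0.03) among those that share reads. For photosystem and electron transport genes, 34 of 34 tested members fell and 0 rose (median −1.11, adjusted p = 5.0e-47). PSAN (−1.56 ± 0.03) and PSBQ2 (−1.42 ± 0.03) fell. In the Calvin cycle, 21 of 21 tested members fell and 0 rose (median −0.73, adjusted p = 1.1e-18), where RBCS2B (−2.06 ± 0.03) and RBCS3B (−1.14 ± 0.03) are near-identical Rubisco small subunit genes of uncertain split. In photorespiration, 14 of 17 tested members fell and 2 rose (median −0.48, adjusted p = 1.3e-05). GS2 (−0.90 ± 0.03) and GLDT (−0.82 ± 0.03) fell and GLU1 (0.20 ± 0.04) rose. Of chlorophyll biosynthesis genes, 21 of 26 tested members fell and 2 rose (median −0.57, adjusted p = 1.7e-08). PORB (−1.54 ± 0.03) fell and HEMA2 (1.74 ± 0.04) rose. Among plastid ribosomal proteins, 25 of 28 tested members fell and 1 rose (median −0.25, adjusted p = 0.0027, and adjusted p = 0.30 with an estimated correlation). PRPL3 (−0.50 ± 0.03) fell. GLK1 (−1.91 ± 0.03) and GLK2 (−1.70 ± 0.03) fell, whereas the plastid RNA polymerase SCA3 (1.23 ± 0.04) and FLN1 (1.15 ± 0.04) rose, and their list was not called (11 of 19 higher and 7 lower, median 0.19, adjusted p = 0.98). Carotenoid metabolism (6 of 15 lower and 3 higher, median −0.0035 and 0.02 under RLE scaling, adjusted p = 0.076) and chlorophyll breakdown (7 of 9 higher and 2 lower, median 0.47, adjusted p = 0.11) were not called. From these, CCD4 (−1.25 ± 0.03) and PSY (−0.93 ± 0.03) fell and NYC1 (0.59 ± 0.03) and PPH (0.49 ± 0.03) rose.

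Stress and hormone lists rose again. In the oxidative stress list, 16 of 16 tested members rose and 0 fell (median 1.09, adjusted p = 6.9e-14), where AOX1D, from 3.85 ± 0.25 to 66.0 ± 1.94 CPM (SD, n = 3), and GSTU24 (3.58 ± 0.10) were highest. Of the salicylic acid genes, 16 of 24 tested members rose and 5 fell (median 0.70, adjusted p = 2.9e-06). FMO1 (3.65 ± 0.15) and ALD1 (2.11 ± 0.11) rose, and WRKY54 (−0.81 ± 0.06) fell. For jasmonate, 18 of 24 tested members rose and 5 fell (median 1.06, adjusted p = 1.5e-17). JAZ10 (2.18 ± 0.05) and LOX3 (2.01 ± 0.03) rose, while VSP2 (−0.67 ± 0.03) fell. Among ethylene and defensin genes, 10 of 14 tested members rose and 4 fell (median 0.52, adjusted p = 5.3e-05, and adjusted p = 0.093 with an estimated correlation), with ACS2 (4.61 ± 0.13) highest and ERF6 (−0.99 ± 0.04) falling. In the abscisic acid list, 14 of 17 tested members rose and 3 fell (median 0.78, adjusted p = 3.1e-08). RD29B (2.15 ± 0.18) and RD20 (1.76 ± 0.03) rose. Of senescence genes, 13 of 17 tested members rose and 3 fell (median 1.12, adjusted p = 2.3e-15). Of heat-shock genes, 11 of 14 tested members rose and 2 fell (median 1.02, adjusted p = 3.3e-05), where the plastid chaperone CLPB3 (−0.26 ± 0.03) fell. Glucosinolate genes were lower. There, 19 of 25 tested members fell and 4 rose (median −0.90, adjusted p = 3.6e-09). MAM3 (−2.45 ± 0.12) and FMOGS-OX3 (−1.61 ± 0.05) fell and MYB122 (4.40 ± 0.46) rose, from 0.055 CPM in wild type to 1.26 CPM.

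Among cell type markers, the vascular list fell in green-white leaves, where 12 of 13 tested members fell and 0 rose (median −0.59, adjusted p = 0.0021). XCP2 (−1.15 ± 0.09) and the phloem gene SEOR1 (−0.98 ± 0.06) fell. For epidermis and trichome markers, 5 of 8 tested members fell and 2 rose (median −0.54, adjusted p = 0.0497, and adjusted p = 0.19 with an estimated correlation). ATML1 (−0.93 ± 0.04) fell and PDF1 (1.92 ± 0.15) rose. This epidermis call ended under RLE scaling (adjusted p = 0.055) and without wild type B, wild type C, green B, green C, green-white A, green-white B, white A, white B and white C taken singly (adjusted p from 0.051 to 0.070). The antioxidant list was not called (11 of 19 higher and 6 lower, median 0.20, adjusted p = 0.071, called at adjusted p = 0.045 without green-white B and 0.048 without green-white C). Anthocyanin (7 of 19 higher and 4 lower, median 0.27, adjusted p = 0.94) and iron (13 of 17 lower and 1 higher, median −0.44, adjusted p = 0.075) were not called. Neither were cell cycle (15 of 19 lower and 0 higher, median −0.78, adjusted p = 0.098) and clock (4 of 12 lower and 4 higher, median −0.02, adjusted p = 0.36, median 0.01 under RLE scaling). Floral (3 of 7 higher and 2 lower, median 0.73, adjusted p = 0.98) and guard cell markers (4 of 7 lower and 0 higher, median −0.42, adjusted p = 0.35) were not called. For flavin-dependent enzymes, also not called, 24 of 54 were higher and 23 lower (median 0.02, adjusted p = 0.23, median −0.05 under upper-quartile scaling). From these lists FSD1 (−2.28 ± 0.03), BHLH39 (−1.07 ± 0.10), NAS4 (−1.07 ± 0.08) and MCM7 (−0.99 ± 0.11) fell, and CSD2 (2.09 ± 0.03), FER1 (1.77 ± 0.04), PRODH1 (2.25 ± 0.04) and TOC1 (1.27 ± 0.04) rose. Over all genes, 14162 changed, 6628 higher and 7534 lower, and 3120 of them also differed at least 2-fold (1616 higher, 1504 lower). Here 46.8% of the changed genes were higher, against 39.6% under upper-quartile factors and 50.2% in a fit of these 6 libraries, so the balance depends on the scaling and the fit. The 3 libraries of one group lay above those of the other for 14518 genes (74.7%, 10% by chance). When adjusted over the list alone, the counts of members differed from those over all genes tested for the photorespiration list (2 higher and 15 lower) and were equal for the other lists. The median, the mean and the test differed in sign for the plastid transcription and regulator list (median 0.19, mean 0.04, test direction down), the clock list (median −0.02, mean 0.10, test direction up) and the floral organ list (median 0.73, mean 0.59, test direction down), none of which was called.

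White leaves, compared with wild type, had the most changed genes of the comparisons with wild type. DIN2 rose from 0.826 ± 0.25 to 229 ± 3.30 CPM (SD, n = 3), a log2 fold change of 8.10 ± 0.07, and the late embryogenesis abundant gene LEA7 (AT1G52690) rose by 7.27 ± 0.14. The seed storage albumin SESA3 (AT4G27160) had no counts in wild type and 714 in white leaves, at least 66.8-fold higher against a floor of 3 counts per library. SUC7 had 1 count in wild type and 1463 in white leaves, a ratio of 1235 (95% counting interval 221 to 48802), and the extensin-like gene EPR1 (AT2G27380) had a ratio of 224 (61.8 to 1859). CIB1 (AT4G34530), with 8.19 ± 0.42 CPM in wild type, had no counts in white leaves, at least 78.1-fold lower, although it overlaps AT4G34540. PYK10 (−6.47 ± 0.10), the expansin EXPB1 (AT2G20750, −6.16 ± 0.28), the glucosinolate chain elongation gene MAM3 (AT5G23020, −6.02 ± 0.20) and FSD1 (AT4G25100, −5.65 ± 0.04) were the other genes among the 5 lowest.

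Photosynthetic lists fell in white leaves. Of the antenna genes, 21 of 21 tested members fell and 0 rose (median −2.10, adjusted p = 1.2e-77), and LHCB4.3 (−3.27 ± 0.07), with whole counts, was among the lowest beside LHCB2.3 (−4.89 ± 0.04) and LHCB1.4 (−4.79 ± 0.03), which share reads with copies. Of photosystem and electron transport genes, 34 of 34 tested members fell and 0 rose (median −1.84, adjusted p = 2.9e-67). PSBQ2 (−2.43 ± 0.03), PSBS (−2.35 ± 0.03) and PSAK (−2.22 ± 0.05) fell. In the Calvin cycle, 20 of 21 tested members fell and 0 rose (median −1.11, adjusted p = 4.4e-28), with the small subunit genes RBCS2B (−4.88 ± 0.04) and RBCS3B (−2.33 ± 0.03) of uncertain split. For photorespiration, 14 of 17 tested members fell and 0 rose (median −0.85, adjusted p = 6.4e-09). GS2 (−2.27 ± 0.03) and GLDT (−1.76 ± 0.03) fell. In chlorophyll biosynthesis, 22 of 26 tested members fell and 3 rose (median −0.51, adjusted p = 1.9e-07). PORA (−2.27 ± 0.14) and PORB (−2.02 ± 0.03) fell and HEMA2 (1.46 ± 0.04) rose. The plastid regulator list rose, and its members moved in both directions. There, 13 of 19 tested members rose and 6 fell (median 0.74, adjusted p = 0.0090, and adjusted p = 0.058 with an estimated correlation), with SCA3 (2.16 ± 0.04) rising, while GLK1 (−3.63 ± 0.04) and GLK2 (−2.44 ± 0.04), which activate photosynthetic genes, fell. Plastid ribosomal proteins (17 of 28 lower and 3 higher, median −0.19, adjusted p = 0.20) and carotenoid metabolism (5 of 15 lower and 6 higher, median −0.01, adjusted p = 0.37, median 0.00 under RLE scaling) were not called. Chlorophyll breakdown was not called either (6 of 9 higher and 3 lower, median 0.56, adjusted p = 0.16). From these, PSY (−1.58 ± 0.03) and CCD4 (−1.44 ± 0.03) fell and NYC1 (1.22 ± 0.03) and SGR2 (1.46 ± 0.08) rose.

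Senescence genes rose in white leaves, where 12 of 17 tested members rose and 2 fell (median 1.51, adjusted p = 1.4e-14). WRKY75 (2.95 ± 0.09) and NAC019 (2.93 ± 0.04) rose, while GLN1;4 (−1.20 ± 0.07) fell. Of the oxidative stress genes, 11 of 16 tested members rose and 1 fell (median 1.11, adjusted p = 1.0e-08), with UGT74E2 (3.95 ± 0.07), AOX1D (3.48 ± 0.07) and UPOX (2.73 ± 0.08) highest. For heat-shock genes, 10 of 14 tested members rose and 2 fell (median 0.75, adjusted p = 0.018, and adjusted p = 0.14 with an estimated correlation). The heat-shock factor HSFA2 (2.80 ± 0.12) rose. In glucosinolate biosynthesis, 23 of 25 tested members fell and 1 rose (median −2.35, adjusted p = 2.5e-29). Besides MAM3, FMOGS-OX3 (−3.56 ± 0.07) and the regulator MYB29 (−3.41 ± 0.09) fell. MYB122 (2.46 ± 0.64) rose, from 0.055 CPM in wild type to 0.33 CPM. In the iron list, 15 of 17 tested members fell and 2 rose (median −1.05, adjusted p = 0.0050). NAS4 (−2.64 ± 0.10) and BHLH39 (−1.92 ± 0.12) fell. Of the vascular markers, 13 of 13 tested members fell and 0 rose (median −1.29, adjusted p = 1.6e-06). XCP1 (−2.13 ± 0.14) and XCP2 (−2.00 ± 0.10) fell.

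Hormone lists were not called in white leaves. They were salicylic acid (13 of 24 higher and 9 lower, median 0.22, adjusted p = 0.15) and jasmonate (13 of 24 higher and 11 lower, median 0.24, adjusted p = 0.86). Likewise uncalled were ethylene and defensins (7 of 14 higher and 6 lower, median 0.01, adjusted p = 0.71, median −0.07 under upper-quartile scaling) and abscisic acid (8 of 17 higher and 6 lower, median 0.03, adjusted p = 0.41, median −0.05 under upper-quartile scaling). Members still moved strongly. ACS2 (5.27 ± 0.12), CYP94B3 (2.14 ± 0.05), RD20 (1.83 ± 0.03) and PBS3 (1.58 ± 0.05) rose and LOX2 (−1.71 ± 0.03), PR1 (−1.55 ± 0.04) and VSP2 (−1.89 ± 0.03) fell. Also uncalled were antioxidants (11 of 19 higher and 7 lower, median 0.44, adjusted p = 0.45) and anthocyanin (9 of 19 lower and 4 higher, median −0.20, adjusted p = 0.45). Cell cycle (16 of 19 lower and 2 higher, median −1.43, adjusted p = 0.083) and clock (7 of 12 higher and 5 lower, median 0.18, adjusted p = 0.16) were not called. The clock list holds morning-phased and evening-phased genes, so a test for a common direction can miss a shift of phase. Harvest times are not in the labels, and a different time of day was not tested for white or green-white leaves. Floral (5 of 7 higher and 1 lower, median 1.59, adjusted p = 0.45) and guard cell markers (2 of 7 lower and 2 higher, median −0.11, adjusted p = 0.71) were not called. The last were epidermis (5 of 8 lower and 2 higher, median −0.37, adjusted p = 0.28) and flavin-dependent enzymes (29 of 54 higher and 21 lower, median 0.22, adjusted p = 0.45). From these, CSD2 (2.50 ± 0.03), PRODH1 (2.68 ± 0.04) and PRR5 (1.35 ± 0.03) rose, and CAT3 (−1.86 ± 0.03), MCM2 (−2.02 ± 0.12), PAP1 (−2.21 ± 0.12) and LHY (−1.93 ± 0.06) fell. SEP2, a floral MADS-box gene, rose by 3.83 ± 0.35 to a level of 1.63 ± 0.13 CPM (SD, n = 3). Over all genes, 15514 changed, 7749 higher and 7765 lower, and 4920 of them also differed at least 2-fold (2079 higher, 2841 lower). The share higher was 49.9%, and 44.1% under upper-quartile factors. Groups did not overlap for 15789 genes (81.3%, 10% by chance). When adjusted over the list alone, the counts of members differed from those over all genes tested for the salicylic acid list (13 higher and 10 lower) and the anthocyanin list (4 higher and 8 lower) and were equal for the other lists. The median, the mean and the test differed in sign for the jasmonate list (median 0.24, mean −0.03, test direction up), which was not called.

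**Figure D1:**
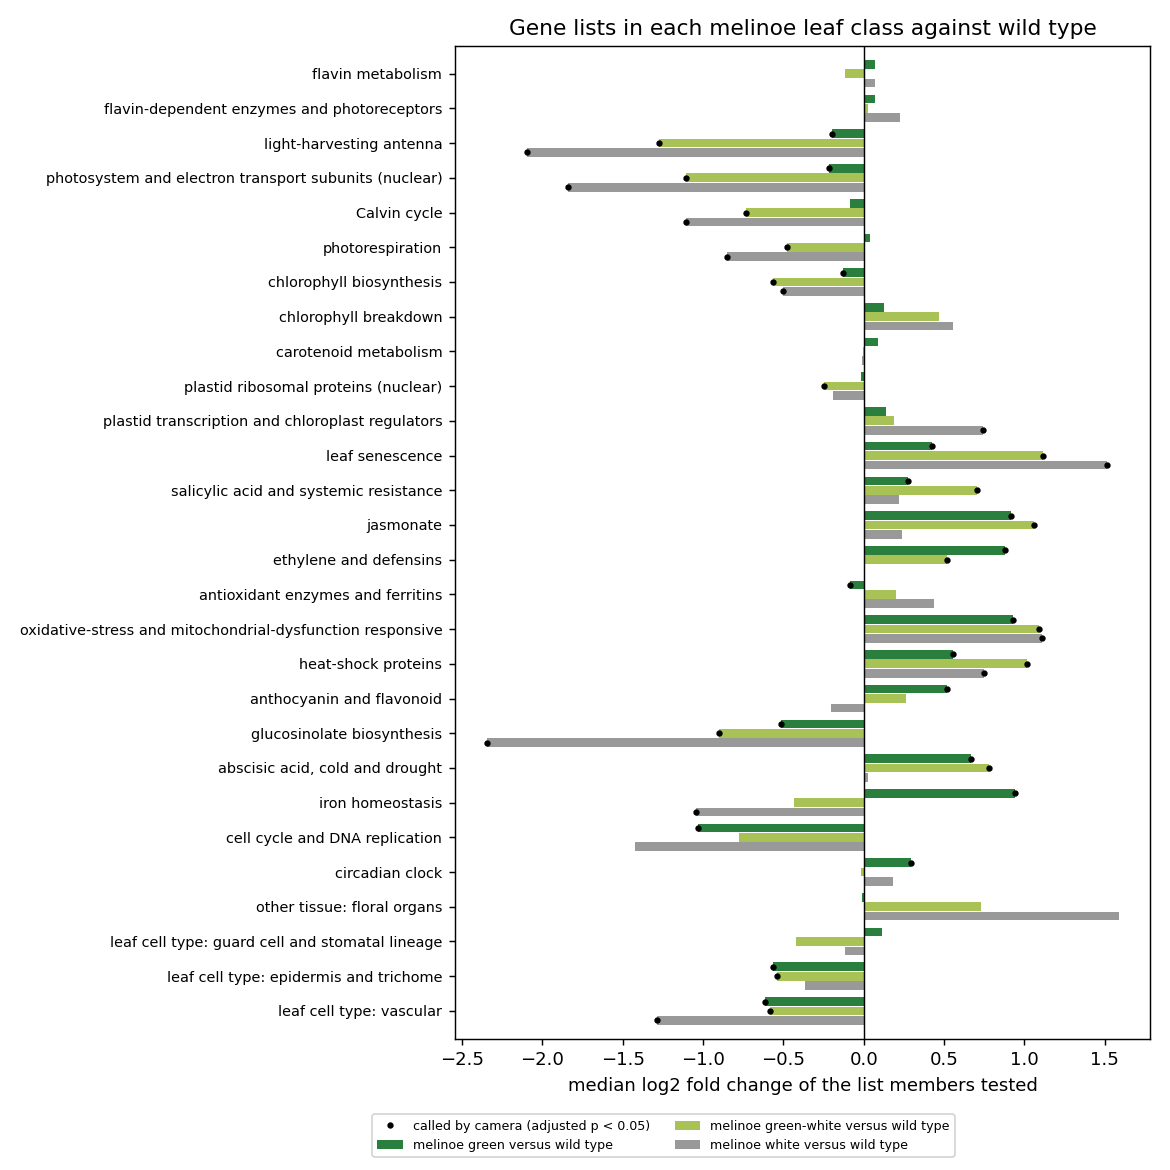
Median log2 fold change of the tested members of each gene list (horizontal axis) in green, green-white and white melinoe leaves, each over wild type. The antenna list goes from −0.20 in green to −1.27 in green-white and −2.10 in white leaves, and the iron list from 0.94 in green to −1.05 in white leaves.

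White against green leaves of the same mutant gave the difference between leaf classes within the genotype. The cruciferin CRU3 (AT4G28520) had no counts in green and 1406 in white leaves, at least 132-fold higher; SESA3 was at least 67.3-fold and EPR1 at least 50.1-fold higher. The vicilin-like PAP85 (AT3G22640) had 2 counts in green and 1538 in white leaves, a ratio of 653 (95% counting interval 181 to 5399.8), and the cruciferin CRA1 (AT5G44120) a ratio of 719.6 (129 to 28457). Among the 5 lowest, CIB1 was at least 86.3-fold lower, and XTH31 (AT3G44990), a xyloglucan-modifying enzyme, fell from 53.6 ± 2.16 to 1.28 ± 0.14 CPM (SD, n = 3), −5.39 ± 0.08 on the log2 scale. PDF1.2c (−5.28 ± 0.05, with shared reads), AACT1 (AT5G61160, −5.26 ± 0.07) and MAM3 (−5.22 ± 0.23) were the others.

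Every photosynthetic list that was lower in white leaves than in wild type was also lower than in green leaves. Of the antenna genes, 21 of 21 tested members fell and 0 rose (median −1.97, adjusted p = 3.6e-101). Of photosystem genes, 34 of 34 tested members fell and 0 rose (median −1.55, adjusted p = 1.2e-77). In the Calvin cycle, 20 of 21 tested members fell and 1 rose (median −1.08, adjusted p = 2.5e-36). For photorespiration, 16 of 17 tested members fell and 0 rose (median −0.85, adjusted p = 3.4e-14). For chlorophyll biosynthesis, 19 of 26 tested members fell and 4 rose (median −0.50, adjusted p = 4.6e-07). PSBS (−2.47 ± 0.03), PSBQ2 (−2.11 ± 0.03), GS2 (−2.03 ± 0.03) and PORB (−1.76 ± 0.03) fell, while HEMA1 (0.53 ± 0.03) and the Calvin cycle epimerase RPE (0.13 ± 0.03) rose. Of the plastid regulators, 13 of 19 tested members rose and 5 fell (median 0.37, adjusted p = 0.00080). FLN2 (1.89 ± 0.04) rose and GLK1 (−2.55 ± 0.04) fell. Senescence genes were higher still. In that list, 14 of 17 tested members rose and 3 fell (median 0.58, adjusted p = 2.4e-16), with DIN2 (4.33 ± 0.05), ASN1 (3.65 ± 0.03) and SAG12 (2.93 ± 0.18) highest. Of the iron genes, 15 of 17 tested members fell and 1 rose (median −1.71, adjusted p = 3.3e-17). BHLH39 (−3.37 ± 0.10) and NAS4 (−2.94 ± 0.10) fell. Among antioxidants, 12 of 19 tested members rose and 7 fell (median 0.36, adjusted p = 0.0060, and adjusted p = 0.13 with an estimated correlation). The ferritins FER1 (2.96 ± 0.05) and FER4 (2.54 ± 0.08) rose and FSD1 (−3.22 ± 0.05) fell.

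The jasmonate, ethylene and abscisic acid lists, higher in green leaves than in wild type, were lower in white than in green leaves. Of the jasmonate genes, 16 of 24 tested members fell and 7 rose (median −0.43, adjusted p = 9.3e-08). TAT3 (−2.75 ± 0.05) and JAR1 (−1.77 ± 0.04) fell, while VSP1 (1.72 ± 0.05) rose. For ethylene and defensins, 10 of 14 tested members fell and 3 rose (median −0.27, adjusted p = 1.2e-05, and adjusted p = 0.075 with an estimated correlation). ORA59 (−2.28 ± 0.07) fell and ACS2 (2.49 ± 0.08) rose. In the abscisic acid list, 12 of 17 tested members fell and 4 rose (median −0.45, adjusted p = 3.4e-06). COR15A (−3.20 ± 0.05) and RD29A (−2.41 ± 0.03) fell and RD29B (2.66 ± 0.14) rose. Of anthocyanin genes, 13 of 19 tested members fell and 2 rose (median −0.91, adjusted p = 0.0012, and adjusted p = 0.077 with an estimated correlation). DFR (−2.62 ± 0.09) and LDOX (−2.37 ± 0.14) fell. In glucosinolate biosynthesis, 23 of 25 tested members fell and 0 rose (median −1.37, adjusted p = 1.0e-25). FMOGS-OX3 (−2.48 ± 0.08) and MYB29 (−2.38 ± 0.11) fell. Of the vascular markers, 7 of 13 tested members fell and 3 rose (median −0.47, adjusted p = 0.00070). The sucrose exporters SWEET11 (−1.35 ± 0.03) and SWEET12 (−1.25 ± 0.04) fell and CESA4 (0.62 ± 0.12) rose. Floral markers were higher in white leaves. There, 6 of 7 tested members rose and 0 fell (median 1.94, adjusted p = 0.038, and adjusted p = 0.085 with an estimated correlation), with SEP1 (3.25 ± 0.14), SEP2 (3.67 ± 0.34) and SEP3 (2.40 ± 0.19) rising, and the call ended without green A (adjusted p = 0.064).

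The lists not called between white and green leaves were flavin metabolism (median 0.12, adjusted p = 0.98), flavin-dependent enzymes (median 0.01, adjusted p = 0.98, median −0.03 under upper-quartile scaling) and carotenoid metabolism (median −0.10, adjusted p = 0.070, called at adjusted p = 0.049 without green A). Chlorophyll breakdown (median 0.15, adjusted p = 0.15), plastid ribosomal proteins (median −0.19, adjusted p = 0.15) and salicylic acid (median 0.05, adjusted p = 0.98) were not called. Nor were oxidative stress (median 0.22, adjusted p = 0.091), heat shock (median 0.09, adjusted p = 0.48) and cell cycle (median −0.22, adjusted p = 0.70). Clock (median −0.20, adjusted p = 0.98), guard cell (median −0.29, adjusted p = 0.59) and epidermis lists (median −0.12, adjusted p = 0.13) were also uncalled. From these lists PRODH1 (3.49 ± 0.04), NYC1 (1.90 ± 0.03), PBS3 (1.18 ± 0.05), UGT74E2 (1.39 ± 0.05) and CER1 (1.88 ± 0.03) rose. FHY1 (−1.42 ± 0.05), PSY (−1.44 ± 0.03), PR1 (−2.26 ± 0.04), GSTU25 (−4.84 ± 0.20) and LHY (−1.52 ± 0.06) fell. Over all genes, 14097 differed, 7041 higher and 7056 lower in white leaves, and 3163 of them also at least 2-fold (1432 higher, 1731 lower). Groups did not overlap for 14372 genes (74.0%, 10% by chance). When adjusted over the list alone, the counts of members differed from those over all genes tested for the cell cycle list (2 higher and 8 lower) and the vascular list (3 higher and 8 lower) and were equal for the other lists. The median, the mean and the test differed in sign for the flavin-dependent enzyme list (median 0.01, mean −0.01, test direction down), the salicylic acid list (median 0.05, mean −0.03, test direction down), the heat-shock list (median 0.09, mean −0.01, test direction up) and the epidermis list (median −0.12, mean 0.31, test direction up), none of which was called.

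From green to green-white leaves, the photosynthetic lists were lower and senescence and stress lists higher. LHCB4.3 (−0.73 ± 0.06), PSBQ2 (−1.10 ± 0.03), GS2 (−0.66 ± 0.03), PORB (−1.28 ± 0.03) and GLK1 (−0.82 ± 0.04) fell, and DIN2 (2.25 ± 0.05), ASN1 (2.56 ± 0.03), AOX1D (1.53 ± 0.05) and FER1 (2.82 ± 0.05) rose. Lists that fell were antenna (21 of 21 lower and 0 higher, median −1.12, adjusted p = 4.8e-78) and photosystem (33 of 34 lower and 0 higher, median −0.93, adjusted p = 2.8e-65). Further such lists were Calvin cycle (20 of 21 lower and 0 higher, median −0.68, adjusted p = 5.4e-30) and photorespiration (15 of 17 lower and 0 higher, median −0.54, adjusted p = 2.6e-12). Also lower were chlorophyll biosynthesis (19 of 26 lower and 3 higher, median −0.41, adjusted p = 3.1e-10) and carotenoid (10 of 15 lower and 1 higher, median −0.17, adjusted p = 0.00027). Others that fell were plastid ribosomal protein (25 of 28 lower and 1 higher, median −0.22, adjusted p = 4.0e-05, and adjusted p = 0.17 with an estimated correlation) and anthocyanin (14 of 19 lower and 3 higher, median −0.62, adjusted p = 0.0020, and adjusted p = 0.085 with an estimated correlation). The same call was given to glucosinolate (18 of 25 lower and 2 higher, median −0.31, adjusted p = 0.0035) and iron (16 of 17 lower and 0 higher, median −1.05, adjusted p = 1.9e-25). Lists that rose were senescence (15 of 17 higher and 1 lower, median 0.67, adjusted p = 6.5e-24) and salicylic acid (17 of 24 higher and 2 lower, median 0.32, adjusted p = 0.00036). Further such lists were jasmonate (15 of 24 higher and 4 lower, median 0.16, adjusted p = 6.5e-05) and antioxidant and ferritin (12 of 19 higher and 5 lower, median 0.16, adjusted p = 2.6e-10). Also higher were oxidative stress (12 of 16 higher and 3 lower, median 0.24, adjusted p = 0.0051) and heat-shock (6 of 14 higher and 1 lower, median 0.23, adjusted p = 0.0060, and adjusted p = 0.080 with an estimated correlation). The other lists were not called, with these medians and adjusted p: flavin metabolism (−0.01, 0.18), flavin-dependent enzyme (0.02, 0.95), chlorophyll breakdown (0.01, 0.080), plastid transcription and regulator (−0.19, 0.95) and ethylene and defensin (−0.33, 0.078). Others were abscisic acid (−0.02, 0.34), cell cycle (0.24, 0.70), clock (−0.23, 0.094), floral organ (0.99, 0.11) and guard cell (−0.44, 0.080). The rest were epidermis (0.06, 0.078) and vascular (0.08, 0.43). The ethylene and defensin list was called without green C (adjusted p = 0.040), and under upper-quartile scaling the medians of chlorophyll breakdown (−0.02), flavin-dependent enzymes (−0.01) and, under RLE, flavin metabolism (0.01) changed sign. In all, 11585 genes differed, 5747 higher and 5838 lower, and 1242 of them at least 2-fold (773 higher, 469 lower). The share higher was 49.6%, against 45.1% under upper-quartile and 52.8% under RLE factors, so this balance depends on the scaling. Groups did not overlap for 12117 genes (62.4%, 10% by chance). When adjusted over the list alone, the counts of members differed from those over all genes tested for the flavin-dependent enzyme list (21 higher and 22 lower), the photorespiration list (1 higher and 15 lower), the carotenoid list (1 higher and 11 lower), the oxidative stress list (12 higher and 4 lower), the cell cycle list (3 higher and 1 lower) and the vascular list (5 higher and 6 lower) and were equal for the other lists. The median, the mean and the test differed in sign for the plastid transcription and regulator list (median −0.19, mean 0.01, test direction down) and the vascular list (median 0.08, mean 0.30, test direction down), none of which was called.

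From green-white to white leaves, antenna and photosystem genes fell further, and the salicylic acid, jasmonate and abscisic acid lists, higher in green-white leaves than in wild type, fell. LHCB4.3 (−1.74 ± 0.08), PSBS (−1.42 ± 0.03), GLK1 (−1.72 ± 0.04), COR15A (−1.76 ± 0.06) and MYB29 (−1.98 ± 0.11) fell, and DIN2 (2.08 ± 0.04), SCA3 (0.93 ± 0.04) and SAG12 (2.27 ± 0.16) rose. Lists that fell were antenna (20 of 21 lower and 0 higher, median −0.85, adjusted p = 4.2e-47) and photosystem (32 of 34 lower and 1 higher, median −0.65, adjusted p = 9.7e-29). Further such lists were Calvin cycle (17 of 21 lower and 1 higher, median −0.44, adjusted p = 5.3e-14) and photorespiration (13 of 17 lower and 3 higher, median −0.32, adjusted p = 2.5e-05). Also lower were salicylic acid (14 of 24 lower and 6 higher, median −0.46, adjusted p = 0.00085) and jasmonate (19 of 24 lower and 3 higher, median −0.90, adjusted p = 2.5e-30). Others that fell were glucosinolate (24 of 25 lower and 0 higher, median −1.54, adjusted p = 4.4e-33) and abscisic acid (12 of 17 lower and 5 higher, median −0.47, adjusted p = 1.8e-08). The same call was given to iron (13 of 17 lower and 2 higher, median −0.48, adjusted p = 0.012) and vascular (11 of 13 lower and 0 higher, median −0.79, adjusted p = 3.9e-05). The ethylene and defensin list was called lower with its members divided, 6 of 14 lower and 5 higher (median −0.08, adjusted p = 7.9e-06, and adjusted p = 0.064 with an estimated correlation), and ERF6 (0.74 ± 0.04) rose. The plastid regulator list rose (16 of 19 higher and 2 lower, median 0.53, adjusted p = 1.4e-06). The senescence list was called higher, also with divided members, 8 of 17 higher and 6 lower (median 0.09, adjusted p = 0.0039), and GLN1;4 (−0.51 ± 0.08) fell. For the lists not called, medians and adjusted p were flavin metabolism (0.20, 0.23), flavin-dependent enzyme (0.03, 0.86), chlorophyll biosynthesis (−0.14, 0.18), chlorophyll breakdown (0.16, 0.59) and carotenoid (0.14, 0.59). Others were plastid ribosomal protein (0.09, 0.17), antioxidant and ferritin (0.11, 0.18), oxidative stress (−0.10, 0.92), heat-shock (−0.42, 0.20) and anthocyanin (−0.21, 0.12). The rest were cell cycle (−0.53, 0.31), clock (0.05, 0.18), floral organ (0.62, 0.14), guard cell (0.15, 0.56) and epidermis (0.17, 0.59). In all, 12475 genes differed, 6497 higher and 5978 lower. The share higher was 52.1%, against 50.5% under RLE factors and 49.9% without any 1 of the wild-type libraries. This balance thus depends on the scaling and the fit. At least 2-fold, 1824 genes differed, of which 573 were higher and 1251 lower. Groups did not overlap for 13198 genes (67.9%, 10% by chance). When adjusted over the list alone, the counts of members differed from those over all genes tested for the salicylic acid list (7 higher and 14 lower) and were equal for the other lists. The median, the mean and the test differed in sign for the flavin-dependent enzyme list (median 0.03, mean −0.04, test direction down), the carotenoid list (median 0.14, mean −0.0028, test direction up) and the antioxidant and ferritin list (median 0.11, mean −0.17, test direction down), none of which was called.

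**Figure D2:**
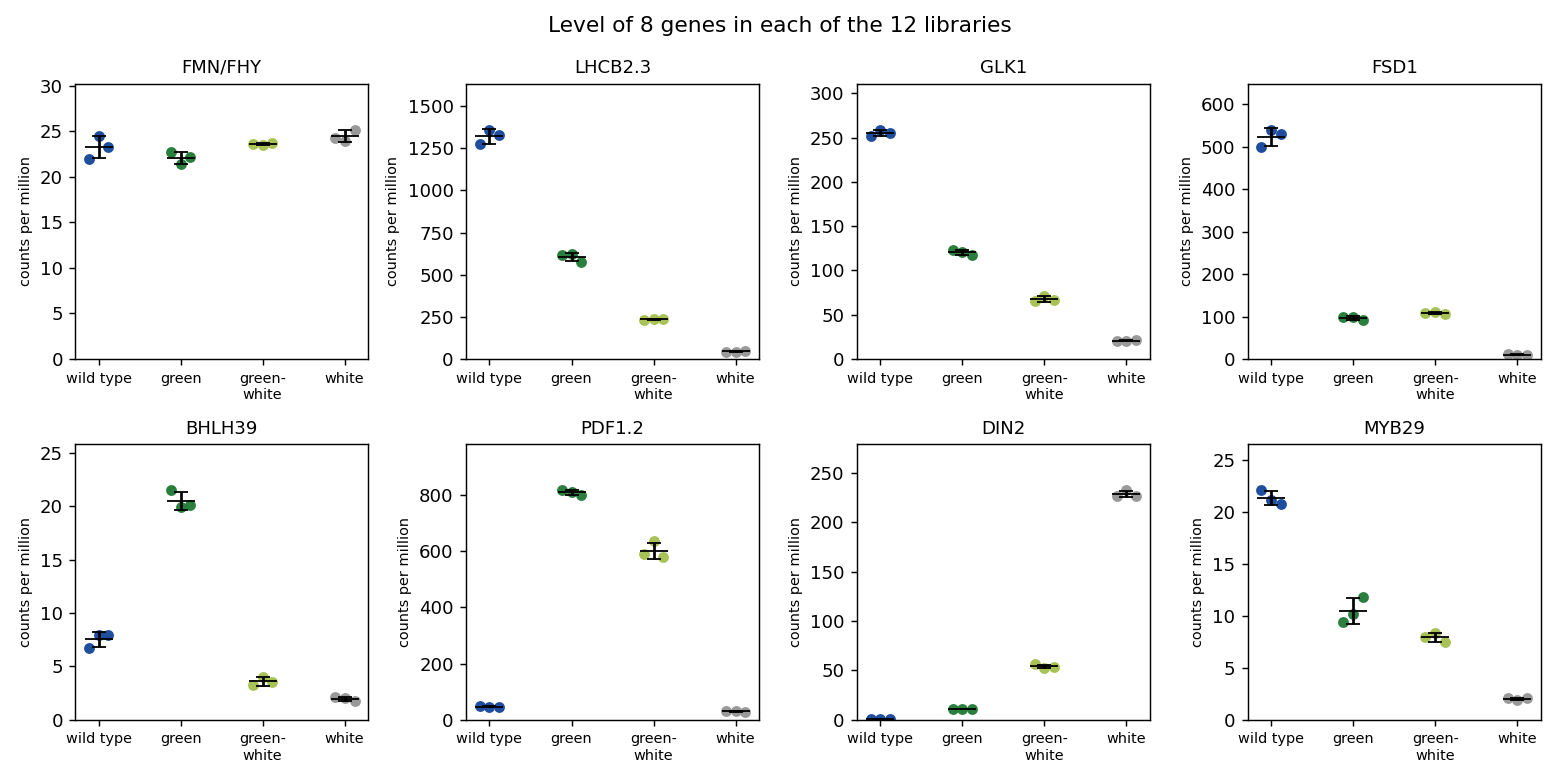
Level of 8 genes in CPM (vertical axes) in wild type and in green, green-white and white melinoe leaves; points are the 3 libraries of a group, bars the mean and whiskers the SD. LHCB2.3 and PDF1.2 share reads with near-identical copies. FMN/FHY stays between 21.4 and 25.2 CPM in all 12 libraries, whereas FSD1 goes from a mean of 523 CPM in wild type to 10.4 CPM in white leaves.

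Genes such as RIBA1, DIN2, GLK1, PYK10 and FSD1 changed in the same direction in all 3 leaf classes against wild type. Green and green-white leaves shared 4064 higher and 4543 lower genes, where independent lists of these sizes would share 1908 and 2238, and 1010 genes were called in opposite directions. Green and white leaves shared 3896 higher and 4463 lower genes against 2231 and 2307, with 1526 opposite. For green-white and white leaves the shared numbers were 5480 and 6144 against 2644 and 3012, with 764 opposite. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.79, 0.63 and 0.83 for these pairs. Unchanged groups simulated against the same wild-type libraries gave r = 0.50, 0.52 and 0.53 over 20 draws. The covariance was 0.542, 0.592 and 0.921, beside 0.0103, 0.0105 and 0.0106 in the simulation, which shared a mean of 0.15, 0.05 and 0.15 calls. These values argue against random spread between the shared wild-type libraries, as simulated, as the source of most of the covariance. A deviation common to all 3 wild-type libraries was not simulated. They were too few to split, so such a deviation can still add to the excess.

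In the authors' deposited table for green leaves, FMN/FHY had a log2 fold change of −0.06 with q = 0.61; their tables gave 0.06 (q = 0.51) for green-white and 0.08 (q = 0.32) for white leaves. The authors' deposited tables held 8866, 12413 and 14779 genes with q under 0.05 in green, green-white and white leaves. Of these genes, 8722, 12102 and 14195 were also called here, each in the same direction as in the authors' deposited tables. A further 2641, 2060 and 1319 genes were called here alone, and 8, 122 and 25 tested genes had q under 0.05 in the authors' deposited tables alone.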

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

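Of the tests in this part, those under other scalings and the counts over other splits of the libraries were chosen only after the result was seen, and the time-of-day, shared-read and vascular tests were set after the list calls were known but before the values of their members were. The iron list moved in opposite directions in green and white leaves, with medians of 0.94 and −1.05 over wild type, and the test of the difference between these leaf classes gave an adjusted p of 3.3e-17 (0.00017 with an estimated correlation). BHLH39 had 1.44 ± 0.08 in green, −1.07 ± 0.10 in green-white and −1.92 ± 0.12 in white leaves, and IMA1 had 1.50 ± 0.06, −0.75 ± 0.08 and −0.99 ± 0.08. Genes called against wild type in opposite directions, and called between the leaf classes themselves, were counted for each pair of classes. Green and green-white leaves had 650 genes higher in green and lower in green-white and 360 the other way, 5 and 9 of them at least 2-fold in both; ASN1 was lower in green (−1.85 ± 0.03) and higher in green-white (0.71 ± 0.03). Green and white leaves had 880 and 646 such genes, 44 and 26 of them at least 2-fold in both, among them COR15A (1.58 ± 0.05 and −1.62 ± 0.06), FER1 (−1.05 ± 0.05 and 1.91 ± 0.04) and SEP1 (−1.69 ± 0.18 and 1.56 ± 0.11). Green-white and white leaves had 394 and 370, 18 and 3 of them at least 2-fold in both. RD29A (1.72 ± 0.03 and −0.68 ± 0.04) was higher in green-white and lower in white leaves.

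The jasmonate, abscisic acid and oxidative stress lists were higher in green leaves than in wild type, in leaves labelled green. The lowest of the medians of these 3 lists was still 0.62 under RLE and upper-quartile factors. Upper-quartile factors moved the median of all genes only from −0.01 to −0.05, so they could hardly have brought these lists to 0. The choice among these scalings thus does not make the increase, and an error common to all of them was not tested. A different time of day at harvest stays open, because the labels give no harvest time. Morning-phased clock genes had a median of 0.03 and evening-phased ones 0.52 (5 genes each), a difference of −0.49 with a spread of 0.25, which lies on neither side of the bound of 0.5 by more than its spread. The mutation itself also stays open and was not tested apart from these.

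The antenna list was lower in white leaves than in wild type. Reads shared between near-identical antenna genes are argued against as the whole cause, since the 12 members with whole counts in at least 11 libraries had a median of −1.83 with a spread of 0.25. The higher of the antenna medians under RLE and upper-quartile factors was −2.08. Upper-quartile factors moved the median of all genes only from −0.0014 to −0.08. The choice among these scalings thus does not make the decrease, and an error common to all of them was not tested. The difference in leaf class stays open as an untested biological explanation.

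The glucosinolate list was lower in white leaves than in wild type, and so were vascular markers. A lower share of vascular tissue as the whole cause is argued against: phloem markers had a median of −1.29 and xylem markers −1.46 (6 genes each), against −2.35 for the glucosinolate genes. The higher of the marker medians lay 1.05 above the glucosinolate median, with a spread of 0.50 over resampled genes, which does not measure variation between libraries. A part of the decrease through vascular tissue, and the leaf class itself, stay open.

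For each of the 6 comparisons, 1 of the 10 splits of its 6 libraries, the real one, gave as many genes, and the highest of the others gave 0. The real splits, fitted on 6 libraries, called 10941, 14066 and 15539 genes for green, green-white and white leaves against wild type, 11133 for green-white and 13826 for white against green leaves, and 12552 for white against green-white leaves. Each other split mixes libraries of both groups, so the group difference enters its spread and leaves few calls in advance. With 10 splits the share also cannot go under 0.1, so these counts do not decide about chance.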

How the results depend on the processing

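The replicate block and the check of letters were chosen after the results were seen, the other alternatives in this part before. No called value of a named gene reversed in the alternatives in which it was tested. The filter of at least 1 CPM in 6 libraries tested 451 of the 484 values. Fits of the 6 libraries compared also left some out. No called list reversed with RLE factors, an estimated correlation, the replicate block or the removal of single libraries. List tests were not run under the other alternatives. The counts of changed genes stayed within 1.5 times of those reported except where a minimum size was added. An adjusted p under 0.05 with at least 2-fold change left 2129, 3120 and 4920 genes for green, green-white and white leaves against wild type, 1242 for green-white against green, 1824 for white against green-white and 3163 for white against green; this follows from the added minimum. With an estimated correlation the lists called in green leaves went from 18 to 9, and the cause was not tested. Without single libraries the changed genes were 10748 to 11418 for green, 13479 to 14383 for green-white and 15136 to 15813 for white leaves against wild type. DESeq2 called 9830, 12813 and 15008. Upper-quartile factors took the median of all genes from −0.01 to −0.05 in green, from −0.04 to −0.11 in green-white and from −0.0014 to −0.08 in white leaves, so list medians under these factors carry that shift. They also lowered the share of changed genes that were higher, to 41.6, 39.6 and 44.1% in green, green-white and white leaves against wild type, from 49.2, 46.8 and 49.9%. Of 484 values of named genes, DESeq2 ended 8 calls, upper-quartile factors 7 (with 2 new calls), RLE factors 1 and the removal of single libraries 44 (with 4 new), counted over genes and libraries. Of 168 list values, 91 called, an estimated correlation ended 22, RLE factors 3 and the removal of single libraries 27 (with 5 new), counted over lists and libraries. Nothing in the labels says that libraries of the same letter share a plant, day or batch, and their deviations from the group means correlated at −0.0400 to 0.0611 over 18 pairs (−0.0669 to 0.0451 for other letters), with 0 of 12 libraries closest to their own letter in all other groups. A replicate block by column letter called 11363, 14149 and 15518 genes for green, green-white and white leaves against wild type, and changed no call of a named gene. It put 3 list calls past 0.05, chlorophyll biosynthesis (adjusted p = 0.053) and senescence (0.053) in green and epidermis (0.051) in green-white leaves. Removing organelle genes was not run, as there were none, and a pseudocount does not apply to counts. Genes with no counts in a group, such as CIB1 in white leaves, have bounds only.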

Other observations

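All tests in this part were chosen after the data were seen. Among 158 annotation terms of 15 to 300 tested genes, some growth terms were lower in melinoe leaves than in wild type. Cell wall loosening genes, which include the expansins, were lower in green leaves (1 of 16 higher and 12 lower, median −0.89, adjusted p = 3.0e-05, 0.033 with an estimated correlation) and did not pass both forms of the test in green-white or white leaves. Genes of microtubule-based processes were lower in green (2 of 15 higher and 10 lower, median −0.57, adjusted p = 8.5e-07, 0.032 with an estimated correlation), green-white (2 of 15 higher and 11 lower, median −0.74, adjusted p = 0.00011, 0.037 with an estimated correlation) and white leaves (1 of 15 higher and 13 lower, median −1.05, adjusted p = 2.5e-05, 0.037 with an estimated correlation), all against wild type. Unidimensional cell growth followed, with medians of −0.43, −0.60 and −0.70 (adjusted p = 0.00014, 0.0032 and 0.00038). Genes of ubiquitin-dependent protein breakdown were higher in green-white (82 of 125 higher and 13 lower, median 0.30, adjusted p = 0.00039, 0.032 with an estimated correlation) and white leaves (91 of 125 higher and 15 lower, median 0.41, adjusted p = 0.00068, 0.037 with an estimated correlation). RNA processing genes were higher in white than in green-white leaves (47 of 66 higher and 3 lower, median 0.30, adjusted p = 0.0013, 0.028 with an estimated correlation). Toxin catabolism, a term that holds glutathione transferases, was lower there (0 of 16 higher and 13 lower, median −0.90, adjusted p = 1.8e-15, 0.022 with an estimated correlation).

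Seed storage transcripts were higher in white leaves than in the other groups. Whether they came from leaf cells or from other tissue in the white samples was not tested. The summed level of 12 seed storage and related genes was 63.3, 66.3 and 68.9 CPM in the white libraries. It was 1.71, 2.16 and 2.16 CPM in green-white, 0.70, 0.78 and 0.94 in green, and 1.15, 1.24 and 0.95 in wild type. The genes were picked because CRU3, SESA3, PAP85 and CRA1 were among the highest in white against green leaves, so the sums describe these libraries and are no independent test.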
